A study of Mus musculus with 18 samples.

How the data were processed

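PolyA RNA libraries were made from brain, kidney and gastrocnemius of old male mice given SeMSNs or saline, with 3 libraries per group and tissue and 18 in all. The deposited table held whole-number counts per gene and library. It also held FPKM values, as deposited by the authors, which had been made by dividing counts by a gene length and the library total. This length could be computed for 17773 genes, from libraries with at least 20 counts, and differed between libraries by a fraction of at most 7.21e-05. The submitters' notes name the GRCm38 genome build; the aligner, the counting tool and the annotation version are not given in the sources used here. The table had 34745 rows, of which 34267 had an identifier in the reference annotation. Symbols that had been turned into dates (27) were named from that annotation. Total counts ranged from 17357799 to 22146406 per library, so 1 count was near 0.06 CPM in brain, and a count of 0 allowed up to 3 counts in a library; this floor covers counting error only. In every tissue the SeMSNs library called replicate 3 carries the number 4 in the submitters' labels.

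Counts of each tissue were fitted alone in R 4.3.3 with edgeR 4.0.16: filterByExpr with a minimum count of 10 and a minimum total of 15, TMM scaling, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled means with SD over 3 libraries. The effect common to the tissues and the differences of effects between tissues were contrasts in an edgeR fit of all 18 libraries with 6 groups. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, for lists with at least 5 tested members, with adjustment over the lists of a tissue, and again with an estimated correlation and with fry. The 76 lists, with 1331 distinct genes, were written from general knowledge before the data were examined.

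The test written before the data were examined was limma on log2(FPKM + 1). For the genes of each tissue the same plan put edgeR in its place if counts were present. For the lists, the common effect and the differences between tissues the plan named limma on log2(FPKM + 1) without that provision, and edgeR and camera on counts were used there as well, a departure from the plan. By the planned test, 16 lists passed in brain, 9 in kidney and 12 in gastrocnemius, 140 genes passed for the common effect, and 2, 1 and 2 genes differed between brain and kidney, brain and gastrocnemius, and kidney and gastrocnemius.

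Genes to name were chosen by a rule written before the data were examined. Per tissue it took up to 10 genes with the largest rise and 10 with the largest fall past the threshold, leaving out predicted and clone-based names, and where fewer passed, the 5 smallest p values in that direction with an absolute log2 fold change of at least 0.58. It added Sik1, Sik2, Sik3, Crtc1, Crtc2, Crtc3, Creb1 and 6 selenoprotein genes in every tissue, and up to 4 members with the smallest p of each list past its threshold and of the selenoprotein, Sik1 pathway, calcium and senescence lists. Genes named for the common effect and for differences between tissues were taken by their p after the values were seen. Some genes that the rule takes are not reported here.

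Alternatives comprised other pseudocounts, filters and scalings, limma and DESeq2 1.42.0, a block for the replicate number, and leaving out each library in turn. Limma on log2(FPKM + 1), the test written beforehand, was run as an alternative where edgeR or camera on counts took its place. Those added after seeing the data were a robust quasi-likelihood fit, removal of a gene length trend in each library, and leaving out both SeMSNs libraries 1 and 2 in brain. Replicate numbers were not treated as pairs: the same number in different tissues had residual correlations between −0.0598 and 0.133 over 18 pairs, of which 4 were over 0.1 and 13 were positive. Their mean was 0.0407, against −0.0202 for different numbers, and the 3 control pairs of kidney and gastrocnemius were at 0.109, 0.111 and 0.124, so tissues taken from the same mice were not excluded. Lengths came from the ratio of counts to FPKM.

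The edgeR fits were tested on simulated data with the same genes. Of genes changed 2-fold, 13% were called in brain, 41% in kidney and 12% in gastrocnemius, and of genes changed 4-fold 81%, 85% and 81%. For the common effect 40% of genes changed 1.5-fold and 94% of genes changed 2-fold were called. For the differences of brain and kidney, brain and gastrocnemius, and kidney and gastrocnemius, 12%, 12% and 11% of 2-fold changes were called. For 4-fold changes these were 79%, 80% and 77%. Unchanged genes made up 5 of 99 calls in brain, 7 of 133 in kidney and 8 of 101 in gastrocnemius. They made up 7 of 141 calls for the common effect, and 7 of 98, 17 of 109 and 11 of 99 for the differences. Simulated lists of 30 members changed 1.5-fold were called in each tissue, also with an estimated correlation. Simulated genes varied independently of each other, while estimated correlations in the real lists were as high as 0.957 (cerebellar list of brain). The simulation therefore does not show how either list test performs on lists of correlated genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.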

Results

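Polyadenylated RNA was sequenced from brain, kidney and gastrocnemius muscle of old male C57BL/6 mice, in 18 libraries: 3 from mice given SeMSNs and 3 from old control mice in each tissue. SeMSNs are described by the submitters as a nano-selenium supplement. Treatment began at 18 months of age, controls received saline by gavage, and tissues were taken at 23 months. The labels disagree on the dose: the design text has 5 mg/kg at 1 mg/mL, given 2 times every 2 days, and the treatment protocol has 10 mg/kg every day. The series links the supplement to Sik1, a salt-inducible kinase, and to calcium homeostasis, so these genes were followed in every tissue beside the selenoproteins and markers of cell types and tissue regions.

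Total counts per library ranged from 17504652 to 18602670 in brain, from 17357799 to 22146406 in kidney and from 18262444 to 20758114 in gastrocnemius. Genes of the mitochondrial genome took 12.5% ± 0.621 (SD, n = 3) of the counts in control brain and 11.1% ± 1.14 in SeMSNs brain. The share was 27.6% ± 1.61 and 26.3% ± 1.77 in kidney, and 24.2% ± 2.05 and 22.9% ± 3.69 in gastrocnemius, for control and SeMSNs. Replicates were distinct libraries: chi-square per degree of freedom between the 18 pairs of replicates lay between 15.8 and 127. The labels do not tie each library to a mouse of its own, so p-values measure the spread between these libraries.

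In brain, the comparison of SeMSNs with old control was dominated by markers of brain regions. Genes of striatal neurons were lower with SeMSNs, with a median log2 fold change of −2.40 and all 16 tested members lower. Among them were the adenosine receptor Adora2a (−4.53 ± 0.749, SE) and the dopamine receptors Drd1 and Drd2 (−3.75 ± 0.833 and −2.77 ± 0.547). Hypothalamic genes, such as the neuropeptide precursors Pmch and Trh, had a median of −3.01, and all 10 tested members were lower. Cerebellar genes such as En2, Neurod1 and Car8 were higher, with a median of 4.0 and all 12 tested members higher.

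The cerebellar difference followed individual libraries: the list lay 5.18 and 5.07 log2 units above the control mean in SeMSNs libraries 1 and 2 and at −0.16 in SeMSNs library 3. The striatal and hypothalamic lists were lower in every SeMSNs library than in any control. The striatal list lay at −2.53, −2.20 and −2.14 with SeMSNs, while control library 2 was at −1.29 and the other controls at 0.47 and 0.82, and the hypothalamic list at −2.66, −3.34 and −3.06, with control library 2 at −1.79 and the other controls at 0.82 and 0.97. The first principal component of the brain libraries held 54.3% of the variance and placed SeMSNs libraries 1 and 2 at 69.6 and 60.4, and the other 4 between −36.5 and −28.8.

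**Figure D1:**
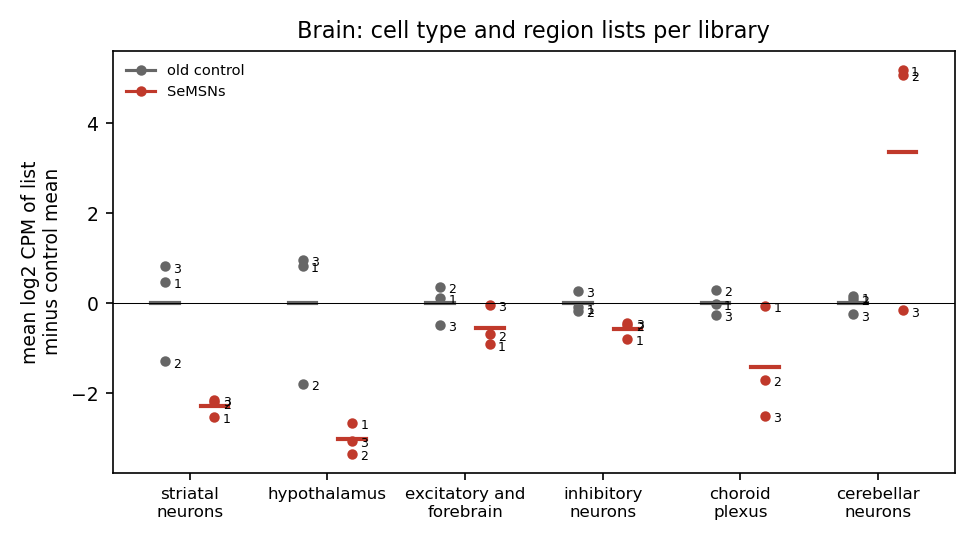
Mean log2 CPM of 6 fixed marker lists in each brain library, relative to the mean of the control libraries. Points are libraries with their replicate number (grey, old control; red, SeMSNs), and bars are group means; the cerebellar list stands at 5.18 and 5.07 in SeMSNs libraries 1 and 2 and at −0.16 in library 3.

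Of 16082 genes tested in brain, Ctdsp2 (ENSMUSG00000078429; GRCm38, chromosome 10, 126978717 to 126999975), which encodes a small CTD phosphatase, rose. It went from 23.3 ± 0.943 CPM (SD, n = 3) in controls to 119 ± 11.4 CPM with SeMSNs. Its log2 fold change was 2.35 ± 0.12 (SE), with an adjusted p of 0.00636 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A low and a high level also occurred within both groups in kidney (27.9, 26.4 and 102 CPM in controls, and 24.3, 101 and 113 CPM with SeMSNs) and within the gastrocnemius controls (34.9, 162 and 94.7 CPM). Its adjusted p by edgeR was 0.103, 0.14, 0.071 and 0.0766 without control library 1, control library 3, SeMSNs library 1 and SeMSNs library 2 in turn, and 0.0633 when all 18 libraries were fitted together; over all its alternatives it ranged from 5.2e-54 to 0.14.

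No gene fell past the threshold in brain, and 1190 genes were higher and 1292 lower at an unadjusted p under 0.05. DESeq2 called 668 genes, 298 higher and 370 lower. The groups did not overlap for 20.8% of genes, where chance gives 10% with 3 libraries against 3. On the higher side the smallest p-values among genes not past the threshold belonged to the tryptophanyl-tRNA synthetase Wars (0.95 ± 0.0934, SE), the transcription factor Pax7 (4.05 ± 0.523), Mab21l2, Hopx and the transcription factor Pou4f2. On the lower side they belonged to Tmem215, Sh2d5, the axon guidance gene Slit2 (−1.21 ± 0.142), Sh3rf2 and Arhgap18. Pax7 and Pou4f2 belong to midbrain development and were near the floor in controls, at 0.154 and 0.0387 CPM. Without SeMSNs library 3, which lacked the cerebellar signal, 2852 genes were called.

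Of 50 gene lists tested in brain with camera, 15 passed, 5 higher and 10 lower. None passed with an estimated correlation between genes, where the lowest adjusted p was 0.727. The striatal list had an adjusted p of 9.72e-18, with 13 members lower adjusted over the list alone and 0 over all genes tested (adjusted p = 0.727 with an estimated correlation). The hypothalamic list had 3.71e-10, with 7 such members (adjusted p = 0.727 with an estimated correlation), and the cerebellar list 1.19e-09, with 11 such members higher (adjusted p = 0.727 with an estimated correlation). Hcrt, which encodes hypocretin, was at 11.9 CPM in controls and had no count in any SeMSNs brain library, which makes it at least 72.1-fold lower against a floor of 3 counts per library. With Hcrt at that bound the hypothalamic median was still −3.01. Choroid plexus genes fell (median −0.90, adjusted p 1.62e-05; adjusted p = 0.727 with an estimated correlation), with list means of −0.06, −1.71 and −2.50 in SeMSNs libraries 1, 2 and 3.

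Nuclear genes of oxidative phosphorylation rose in brain, with a median of 0.29 and 57 of 58 members higher, among them Ndufb2 (0.59 ± 0.137) and Cyc1 (0.43 ± 0.119); 0 passed over the list alone or over all genes tested. The list's adjusted p was 1.05e-07 (adjusted p = 0.727 with an estimated correlation), and 0.101 without SeMSNs library 3. Type I interferon genes rose by a median of 0.90, with 28 of 29 members higher, including Stat2 and Ifi27; 0 passed over the list alone or over all genes tested. Their list mean was 1.72, 0.49 and −0.23 in SeMSNs libraries 1, 2 and 3, and the adjusted p was 1.62e-05 (adjusted p = 0.727 with an estimated correlation), or 0.157 without SeMSNs library 1. MHC class I genes rose beside them (median 0.50, adjusted p 0.00491; adjusted p = 0.727 with an estimated correlation), with H2-D1 at 1.16 ± 0.397 and 0 members past the threshold over the list alone, and had an adjusted p of 0.0986 without SeMSNs library 1. By limma the MHC list had 0.0832 on log2(FPKM + 0.1), 0.0775 on log2(FPKM + 1) and 0.0567 after quantile normalisation.

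Some lists of neuronal genes fell in brain, while the list of general neuronal genes was near 0 (median −0.02). Synaptic plasticity genes (median −0.32, adjusted p 0.00275), with Ntrk2 at −0.57 ± 0.133, excitatory and forebrain markers (−0.43, 0.00905), with Wfs1 and Lamp5, and inhibitory markers (−0.74, 0.00989), with Gad2 and Erbb4, each had an adjusted p = 0.727 with an estimated correlation. Adjusted over the list alone, 0, 3 and 3 of their members passed, and 0 over all genes tested. The synaptic and excitatory list means in SeMSNs library 3 were 0.12 and −0.04, inside the control ranges of −0.17 to 0.22 and −0.48 to 0.37. These falls came from SeMSNs libraries 1 and 2 (−0.85 and −0.58, −0.91 and −0.69), the libraries with the cerebellar signal. The inhibitory list was at −0.79, −0.48 and −0.45 with SeMSNs and between −0.17 and 0.27 in controls. Whether uneven brain pieces account for the falls was not tested. The synaptic list had an adjusted p of 0.0702 without control library 2 and 0.0916 without SeMSNs library 1, the excitatory list 0.152 without control library 2, and the inhibitory list 0.0659 without SeMSNs library 3. Immediate early genes fell (median −0.39, adjusted p 0.0101; adjusted p = 0.735 with an estimated correlation), and had an adjusted p of 0.407 without control library 2 and 0.134 without SeMSNs library 2. Genes of the mitochondrial genome, red blood cells and oligodendrocyte precursors fell and cytosolic ribosomal proteins rose, with adjusted p values of 0.0101, 0.0207, 0.0386 and 0.0383 (adjusted p = 0.727, 0.727, 0.727 and 0.892 with an estimated correlation). The mitochondrial list had an adjusted p of 0.106 without control library 2 and 0.108 without SeMSNs library 2. The red blood cell list had 0.207, 0.301, 0.0921 and 0.294, without control libraries 1 and 3 and SeMSNs libraries 1 and 3 in turn, and the precursor list had 0.119, 0.061, 0.143 and 0.105, without control libraries 1 and 3 and SeMSNs libraries 1 and 2 in turn. The ribosomal list had 0.356 without control library 2, and its direction reversed without SeMSNs library 3 (0.761). By limma after quantile normalisation the mitochondrial, red blood cell and ribosomal lists had 0.819, 0.0525 and 0.0815, and the ribosomal list had 0.0593 on log2(FPKM + 0.1) and 0.0511 on log2(FPKM + 1). With the length trend removed the precursor and ribosomal lists had 0.0579 and 0.0962. Lists of general neuronal, oligodendrocyte and myelin, astrocyte and microglial genes were not past the threshold.

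In kidney, genes of macrophages and of endothelial cells fell with SeMSNs. The macrophage list had a median of −0.51, and 19 of 22 members were lower, among them the perforin-like gene Mpeg1 (−0.61 ± 0.127, SE), the surface receptor Adgre1 (−1.34 ± 0.288), the Fc receptor Fcgr3 and the complement gene C1qb. The list mean was −0.51, −0.54 and −0.44 in the 3 SeMSNs libraries and between −0.12 and 0.14 in controls. The endothelial list had a median of −0.44 with 14 of 16 members lower, including Pecam1 (−0.58 ± 0.133), Ptprb, Flt1 and Cdh5. Adjusted over the list alone, 10 macrophage and 3 endothelial genes passed, and 0 over all genes tested.

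By camera the macrophage list had an adjusted p of 6.34e-11 (adjusted p = 0.236 with an estimated correlation) and the endothelial list 4.7e-08 (adjusted p = 0.995 with an estimated correlation). Both stayed past the threshold in each of the 6 fits that left out a library. Markers of T and NK cells, fibroblasts, podocytes, smooth muscle and proximal tubule, with medians of −0.18, 0.07, 0.04, 0.21 and 0.05, were not past it. Other splits of the kidney libraries called 12 to 22 lists by camera, against 10 for the real groups. A kidney list past the threshold with the preset correlation therefore does not by itself set the groups apart.

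Cholesterol synthesis genes fell in kidney by a median of 0.22 on the log2 scale, with 18 of 22 members lower. The sterol sensor partner Insig1 (−0.67 ± 0.147), squalene synthase Fdft1 (−0.46 ± 0.107) and Msmo1 were among the members that passed adjusted over the list alone, and 0 passed over all genes tested. The adjusted p was 2.37e-05 (adjusted p = 0.998 with an estimated correlation). Tubular injury genes fell too (median −0.67, 21 of 22 lower, adjusted p 1.05e-07; adjusted p = 0.998 with an estimated correlation), including C3, Vcam1 and Havcr1, which encodes a marker of injured tubules; 0 members passed over the list alone or over all genes tested. Control library 3 carried much of this difference, with a list mean of 0.65 against −0.49 and −0.16 in control libraries 1 and 2. The SeMSNs libraries were at −0.398, −0.565 and −0.746, so the groups overlapped, with control library 1 below SeMSNs library 1. Without control library 3 the list was still past the threshold by camera (adjusted p 0.0427), as it was in the other 5 fits that left out a library.

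Immediate early genes (median −0.59), senescence and secretory genes (−0.32) and neutrophil genes (−0.89) fell in kidney, with adjusted p values of 0.000463, 0.0163 and 0.019 (adjusted p = 0.998 with an estimated correlation for each). All 3 rested on control library 3, whose list means were 1.07, 0.51 and 0.85. Without it their adjusted p values were 0.827 with the direction reversed, 0.555 and 0.404. Immediate early and neutrophil genes also had 0.0696 and 0.187 without SeMSNs library 3, and senescence genes 0.0531 without SeMSNs library 1. Oxidative phosphorylation and ribosomal protein genes rose by medians of 0.11 and 0.09 (adjusted p 0.0406 and 0.0423; adjusted p = 0.998 with an estimated correlation for both). Without SeMSNs library 2 both reversed, with adjusted p values of 0.745 and 0.468. The first had 0.265 and 0.365 without control libraries 2 and 3, and the second 0.922 without control library 3. SeMSNs library 2 also stood lowest for markers of medulla and papilla, with a list mean of −1.20 against −0.249 to 0.164 in the other libraries. Whether this bears on the 2 rises was not tested. The Sik1, CREB and CRTC pathway list fell by a median of 0.19 on the log2 scale, with 21 of 29 members lower and 0 past the threshold over the list alone (adjusted p 0.0423; adjusted p = 0.998 with an estimated correlation). Its adjusted p was 0.365, 0.117 and 0.104 without control library 3, SeMSNs library 2 and SeMSNs library 3 in turn. The pathway list shares Sik1, Nr4a1, Nr4a2 and Nr4a3 with the immediate early list. By limma on log2(FPKM + 0.1), on log2(FPKM + 1) and after quantile normalisation the senescence list had 0.157, 0.111 and 0.215 and the Sik1 pathway list 0.247, 0.215 and 0.26, and after quantile normalisation the oxidative phosphorylation and ribosomal lists had 0.127 and 0.0637. With the length trend removed the senescence, neutrophil, oxidative phosphorylation, ribosomal and Sik1 pathway lists had 0.0569, 0.0533, 0.323, 0.293 and 0.248.

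**Figure D2:**
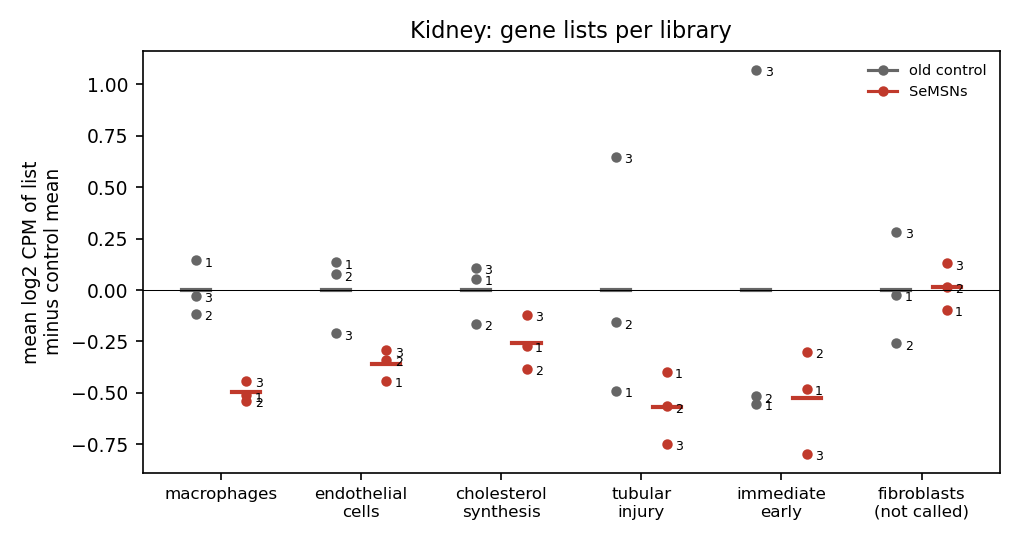
Mean log2 CPM of 6 fixed gene lists in each kidney library, relative to the mean of the control libraries. Points are libraries with their replicate number (grey, old control; red, SeMSNs), and bars are group means; the macrophage list is between −0.54 and −0.44 in the SeMSNs libraries, and control library 3 is at 1.07 for immediate early genes.

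Of 15051 genes tested in kidney, Eva1a (ENSMUSG00000035104; chromosome 6, 82041043 to 82093099, overlapped by the antisense Gm15864), a gene of autophagy and programmed cell death, fell from 45.1 ± 1.93 CPM (SD, n = 3) to 14.6 ± 2.02 CPM. Its log2 fold change was −1.62 ± 0.136 (SE), with an adjusted p of 0.0429 in edgeR's quasi-likelihood test. The adjusted p of Eva1a was between 0.0719 and 0.238 in the 5 fits without control library 1, 2 or 3 or SeMSNs library 1 or 3, and 0.0378 without SeMSNs library 2, within a range of 8.13e-18 to 0.361 over all its alternatives. No gene rose past the threshold; 380 were higher and 540 lower at an unadjusted p under 0.05, and DESeq2 called 26, 8 higher and 18 lower. Next in order, and not past the threshold, were BC003331 (1.19 ± 0.12), Sec22c, Josd2, Trim7 and Med15 on the higher side and Tmem9 (−1.15 ± 0.12), Umad1, the complement protease C1s1, Zfp180 and Smim8 on the lower side. The groups did not overlap for 13.5% of genes, against 10% by chance.

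In gastrocnemius, Sik1 and the insulin receptor substrate Irs2 fell with SeMSNs. Sik1 (ENSMUSG00000024042; chromosome 17, 31844248 to 31855792) went from 110.5 ± 15.4 CPM (SD, n = 3) in controls to 24.3 ± 5.15 CPM, a log2 fold change of −2.19 ± 0.218 (SE). Irs2 (ENSMUSG00000038894; chromosome 8, 10986980 to 11008458, overlapped by the antisense 9530052E02Rik) went from 50.8 ± 14.3 CPM to 7.23 ± 2.34 CPM, a log2 fold change of −2.81 ± 0.295. Their adjusted p values in edgeR's quasi-likelihood test were 0.0246 and 0.0248. A model of the myosin heavy chain gene Myh14 (ENSMUSG00000108439) fell by 6.51 ± 0.448, with an adjusted p of 0.00219 by edgeR, but it overlaps a second Myh14 model on the same strand and is uncertain.

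Immediate early genes fell as a group in gastrocnemius, with a median of −1.03 and 19 of 20 members lower. Besides Sik1 they included the nuclear receptor Nr4a3 (−2.68 ± 0.708), Fosl2, Junb and Btg2; 9 passed adjusted over the list alone and 1 over all genes tested. The list's adjusted p was 1.43e-11 (adjusted p = 0.501 with an estimated correlation). The list of Sik1, CREB and CRTC pathway genes fell by a median of 0.29 on the log2 scale, with 22 of 29 members lower and 3 passing adjusted over the list alone (Sik1, Ppargc1a and Nr4a3), 1 over all genes tested. Its adjusted p was 3.28e-05 (adjusted p = 0.501 with an estimated correlation). Sik1, Nr4a1, Nr4a2 and Nr4a3 are members of this list and of the immediate early list, so the falls of these lists are not separate results. The coactivator gene Crtc2 was at −0.67 ± 0.216, with an adjusted p of 0.312 by edgeR.

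Muscle atrophy genes fell (median −0.66, adjusted p 3.68e-07; adjusted p = 0.501 with an estimated correlation). Of 21 members 18 were lower, among them the ubiquitin ligase Trim63 (−1.51 ± 0.254) and the metallothioneins Mt1 and Mt2; 6 passed adjusted over the list alone and 0 over all genes tested. Genes induced by glucocorticoids, by denervation and by p53 fell by medians of 0.42, 0.41 and 0.41 on the log2 scale, with adjusted p values of 0.000231, 0.000282 and 0.00409 (adjusted p = 0.598, 0.598 and 0.501 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21 and belongs to all 3 lists, was at −2.21 ± 0.307 and not past the threshold over all genes tested (adjusted p 0.117 by edgeR). The glucocorticoid list had an adjusted p of 0.058 without control library 3, and the denervation list 0.064 without control library 1. By limma the denervation list had 0.183 on log2(FPKM + 0.1), 0.164 on log2(FPKM + 1) and 0.171 after quantile normalisation, and the p53 list 0.0585 after quantile normalisation.

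Nuclear genes of oxidative phosphorylation rose in gastrocnemius, with a median of 0.47 and 56 of 58 members higher. Ndufb2 (0.72 ± 0.188), Atp5g1 (0.67 ± 0.173) and Ndufab1 (0.61 ± 0.163) led the list; 32 members were higher at an unadjusted p under 0.05, and 0 passed over the list alone or over all genes tested. The adjusted p was 4.8e-16 (adjusted p = 0.566 with an estimated correlation). Genes of the mitochondrial genome were not past the threshold (median −0.05, adjusted p 0.814). Fast IIb fibre genes rose beside them (median 0.57, 15 of 16 higher, adjusted p 7.03e-06; adjusted p = 0.555 with an estimated correlation), with Mylpf, Pvalb and Casq1 and 0 members past the threshold over the list alone, as did ribosomal protein genes (median 0.25, adjusted p 5.88e-05; adjusted p = 0.802 with an estimated correlation).

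Slow fibre genes fell (median −0.96, adjusted p 0.00231; adjusted p = 0.802 with an estimated correlation), but their list mean was 1.31, 0.18 and −1.49 in the controls and −0.57, −1.66 and −0.10 with SeMSNs, and the adjusted p was 0.832 without control library 1 and 0.0953 without SeMSNs library 2. Genes of Schwann cells and nerve, macrophages, tendon and cartilage, and endoplasmic reticulum stress fell and type I interferon genes rose, with adjusted p values of 0.00285, 0.0128, 0.0148, 0.0486 and 0.021 (adjusted p = 0.802, 0.802, 0.598, 0.802 and 0.802 with an estimated correlation). The Schwann cell list had an adjusted p of 0.0907 without control library 2. The macrophage list had 0.358 without control library 3 and 0.0989 without SeMSNs library 3, the tendon list 0.151 without control library 3 and 0.139 without SeMSNs library 1, and the interferon list 0.0706 without control library 1 and 0.626 without SeMSNs library 1. The endoplasmic reticulum list had 0.129, 0.255, 0.108 and 0.0853 without control libraries 1 and 2 and SeMSNs libraries 2 and 3 in turn. By limma on log2(FPKM + 0.1) and log2(FPKM + 1) the macrophage list had 0.053 and 0.0577 and the tendon list 0.106 and 0.136, with 0.126 for the tendon list after quantile normalisation. The interferon list had 0.055 with the length trend removed.

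**Figure D3:**
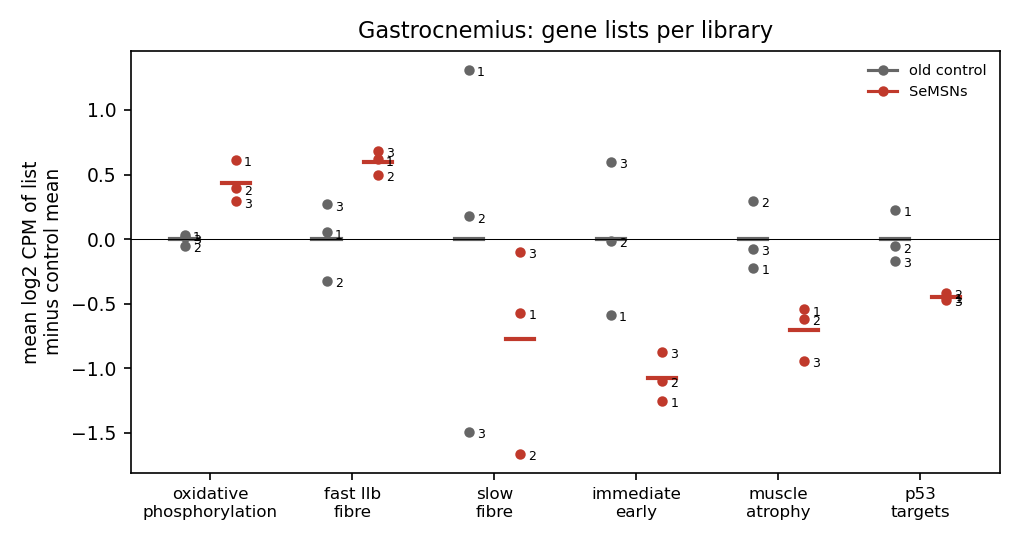
Mean log2 CPM of 6 fixed gene lists in each gastrocnemius library, relative to the mean of the control libraries. Points are libraries with their replicate number (grey, old control; red, SeMSNs), and bars are group means; immediate early genes lie between −1.25 and −0.87 in the SeMSNs libraries and between −0.59 and 0.60 in controls.

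Of 13150 genes tested in gastrocnemius, 3 fell and 0 rose by edgeR, while 824 were higher and 883 lower at an unadjusted p under 0.05, and DESeq2 called 162, 37 higher and 125 lower. The lower side went on with the arginine transporter Slc7a1 (−1.56 ± 0.198), the calcineurin regulator Rcan1 (−1.43 ± 0.207), Pvr and Srxn1, and the higher side began with Emid1, Cntfr, Sytl2, Mrps21 and Uqcc2, none past the threshold. Adjusted p values of Sik1 were 0.0935, 0.0528, 0.209 and 0.219 by edgeR, and those of Irs2 0.0935, 0.128, 0.256 and 0.0922, without control library 2 and SeMSNs libraries 1, 2 and 3 in turn. Over all their alternatives the adjusted p ranged from 4.16e-16 to 0.219 for Sik1 and from 4.16e-16 to 0.256 for Irs2. These alternatives do not include fits with a fibre score as a covariate. With the fast IIb fibre score the adjusted p was 0.326 for Sik1 and 0.412 for Irs2 by edgeR. The log2 fold change of Sik1 stayed between −2.35 and −2.0 under every alternative run. The Myh14 model had an adjusted p of 0.0922 by edgeR without SeMSNs library 3. Without control library 3, 335 genes were called. The groups did not overlap for 18.5% of genes, against 10% by chance.

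Selenoprotein genes as a list were not past the threshold in brain, kidney or gastrocnemius, with medians of 0.02, 0.05 and 0.02 and adjusted p values of 0.576, 0.973 and 0.863; the kidney list had a positive median, a mean of −0.02 and a test direction of higher, and the gastrocnemius list a positive median, a mean of −0.20 and a test direction of lower. Genes of selenium handling and selenoprotein synthesis were not past it either; in brain that list had a median of 0.04, a mean of −0.11 and a test direction of lower. In kidney, Gpx1 was between 150 and 475 CPM in 5 libraries and at 2470 CPM in SeMSNs library 2. Gpx3, Gpx4, Txnrd1, Sepp1 and Sepw1 were not past the threshold in any tissue. The 3 calcium lists (channels and release, pumps and exchangers, binding and calmodulin signalling) were not past the threshold in any tissue. Single members passed by edgeR for the effect common to the tissues, given below. Of the calcium lists these were Rcan1 (−0.957, adjusted p 0.029) and Trpv4 (−0.47, 0.0456), and of the senescence list Cdkn1a (−1.18, 0.0419). The calls for that effect depended on single libraries, as given there. Senescence genes passed in kidney alone of the 3 tissues, a difference between tissues that was not tested. Sik1 was at −1.13 ± 0.245 in brain and −0.13 ± 0.29 in kidney, with adjusted p values of 0.255 and 0.927 by edgeR; in kidney it was at 0.34 without control library 3 (0.338, adjusted p 0.724).

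**Figure D4:**
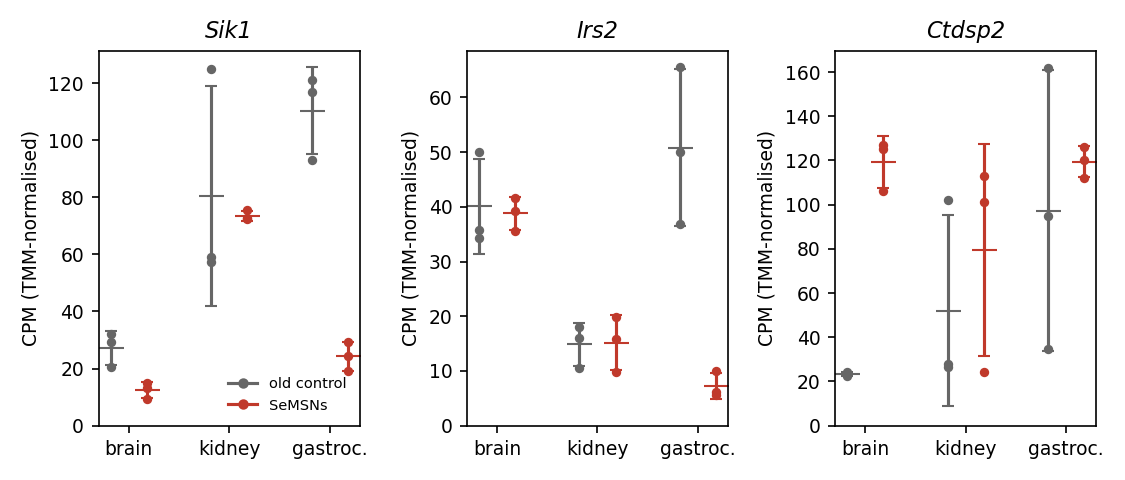
Normalised CPM of Sik1, Irs2 and Ctdsp2 in the 18 libraries by tissue and group. Points are libraries, horizontal marks are means and bars are SD (n = 3; grey, old control; red, SeMSNs); Sik1 in gastrocnemius is between 19.1 and 29.4 CPM with SeMSNs and between 92.9 and 121 CPM in controls.

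The effect common to the tissues was tested as the mean of the 3 log2 fold changes in a fit of all 18 libraries. Of 12124 genes, 165 passed by edgeR, 66 higher and 99 lower. Of the 165, 155 had the same direction in all 3 tissues, which a test of the mean favours. The mean includes brain, where region markers differed between the groups. The striatal marker Adora2a passed (−1.46, adjusted p 0.0461 by edgeR) with −4.53 in brain, −0.09 in kidney and 0.26 in gastrocnemius. How far brain regions entered the other calls was not tested. Echdc2, a mitochondrial enoyl-CoA hydratase family gene, was highest in the order of p, at 1.01 ± 0.131 (SE), with 1.76 in brain, 0.57 in kidney and 0.74 in gastrocnemius. Sik1 followed at −1.16 ± 0.16, with −1.13, −0.13 and −2.19 in the same tissues, though the kidney value was 0.34 (0.338) without control library 3; the Myh14 model, Echdc2 and Sik1 shared an adjusted p of 0.00756 by edgeR. Filip1, the thrombin receptor F2r (−0.84 ± 0.127), Kdsr, Slc7a1 and Irs2 fell, and the haem synthesis gene Ppox (0.42 ± 0.0694) and the mitochondrial gene Clybl rose. Irs2, Kdsr and the Myh14 model drew most of their mean from gastrocnemius, since they were at −0.05, −0.05 and −0.30 in brain and at 0.03, −0.10 and −0.13 (−0.125) in kidney. Without SeMSNs library 2 of every tissue Echdc2 and Sik1 had an adjusted p of 0.118, the Myh14 model 0.059, and the other 7 genes 0.118 to 0.163. Those 7 had 0.124 to 0.149 without SeMSNs library 1, and all of them but F2r had 0.0505 to 0.11 without control library 2. By limma on log2(FPKM + 1) Kdsr had 0.0614 and the Myh14 model 0.0501, and with the length trend removed Clybl had 0.0531.

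All 58 oxidative phosphorylation genes had a positive common effect, with a median of 0.27, and Ndufab1, Ndufb2, Cyc1 and Atp5g1 rose past the threshold over all genes tested. The split by direction changed when limma on FPKM replaced edgeR on counts, which changed the test and the scale together. Limma on log2(FPKM + 1), the test written for this effect before the data were examined, called 109 higher and 31 lower, and with a pseudocount of 0.1 it called 121 and 45. With the replicate number within each treatment as a random effect, as if equal numbers were 1 mouse, it called 149 and 49, and after quantile normalisation 189 and 108. By edgeR the lower side stayed larger, with 39 and 48 at a mean FPKM of at least 5 and 49 and 76 with the length trend removed. The count of 165 was 10, 8, 1 and 640 with control library 2, SeMSNs library 1, SeMSNs library 2 and SeMSNs library 3 of every tissue left out in turn.

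**Figure D5:**
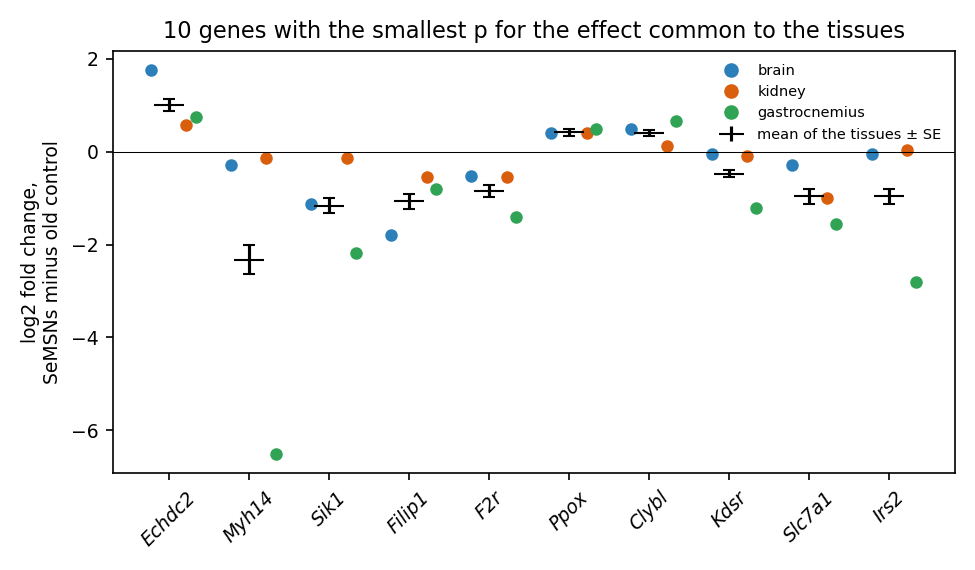
Log2 fold change, SeMSNs minus old control, of the 10 genes with the smallest p for the effect common to the tissues. Black marks with bars are the mean over the tissues ± SE and coloured points are brain, kidney and gastrocnemius; Echdc2 is at 1.76, 0.57 and 0.74, and Irs2 is far from 0 in gastrocnemius.

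Differences of the effect between tissues were tested as interactions, and genes are said to differ where they passed the threshold. By the relabellings given further on, chance was not excluded for the count of any pair. In simulated data, unchanged genes made up 17 of 109 calls for brain and gastrocnemius, so some genes named for that pair may be false calls. Brain and kidney differed for 2 of 13545 genes, Eva1a and the transcription factor gene Tfap2b (adjusted p 0.045 for both). Without control libraries 2 and 3 and SeMSNs libraries 1 and 2 of every tissue in turn, Eva1a had 0.0848, 0.186, 0.33 and 0.402 and Tfap2b 0.15, 0.261, 0.33 and 0.402, and Tfap2b had 0.101 without control library 1. Both had 0.0991 by limma on log2(FPKM + 0.1), and Tfap2b had 0.387 on log2(FPKM + 1) and 0.275 after quantile normalisation. Brain and gastrocnemius differed for 19 of 12556 genes, 12 with the higher effect in brain, among them Irs2, Pax7 and the sphingosine kinase gene Sphk1, and 7 with the lower effect in brain, among them Sh3rf2 and Adora2a. These 5 had adjusted p values of 0.0915 to 0.263 without SeMSNs library 1 and 0.151 to 0.212 without SeMSNs library 2. Pax7, Sphk1 and Adora2a had 0.167 to 0.183 without control library 1, and Pax7 and Sphk1 had 0.0515 and 0.12 without control library 2. By limma on log2(FPKM + 1), the test written for these differences before the data were examined, 1 gene differed between brain and gastrocnemius, and 2 genes for each of the other pairs. Kidney and gastrocnemius differed for Irs2 and the Myh14 model, 2 of 12399 genes (adjusted p 0.0221 and 0.0089). Irs2 had 0.103, 0.0894, 0.378 and 0.0644 without control libraries 1 and 2 and SeMSNs libraries 1 and 2 in turn. The Myh14 model had 0.0755, 0.0894, 0.148 and 0.0873 without control libraries 1 and 2 and SeMSNs libraries 1 and 3 in turn, 0.266 by limma on log2(FPKM + 1) and 0.204 after quantile normalisation. For Sik1 the difference between kidney and gastrocnemius was 2.07 ± 0.389, with an adjusted p of 0.12 by edgeR and 0.0408 by limma on log2(FPKM + 1), within a range of 0.00672 to 0.568 over its alternatives.

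Across genes, which are not independent replicates, the effects of brain and kidney had a Pearson r of 0.0992 and a Spearman rho of 0.158, those of brain and gastrocnemius 0.117 and 0.175, and those of kidney and gastrocnemius 0.279 and 0.295. On log2 CPM, the scale on which other splits of the same libraries were computed, the real r was 0.0978, 0.13 and 0.242 and the highest r of another split 0.107, 0.16 and 0.256, so none of the 3 pairs exceeded it. Without control library 3 the value for kidney and gastrocnemius was 0.0789. The covariance of effects on log2 CPM was 0.015, 0.0272 and 0.0325 with the real labels, above the highest of the 9 other splits (0.00858, 0.015 and 0.0276). So few splits cannot give a share under 0.05. Of 100 relabellings with each tissue split on its own, the real one included, 8, 8 and 6 gave an absolute r as large.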

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

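The tests of handling or time of day, of length bias in brain and in kidney, of a length trend shared by the tissues, and of other splits within each tissue or with equal numbers kept together were chosen only after the results were seen; an earlier draw of relabellings over the 18 libraries was replaced after its counts had been seen, because it had left out mirrored labels, and genes that were in a fixed list were left out of the tests of hindbrain and of fasting genes after their values had been seen, to hold to the tests as written.

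The following genes passed the threshold for a difference of the treatment effect between tissues, each by an interaction test in edgeR with Benjamini-Hochberg adjustment. Values are differences of log2 fold changes. Some may be false calls: in simulated data, unchanged genes made up 17 of 109 calls for brain and gastrocnemius and 11 of 99 for kidney and gastrocnemius. They made up 7 of 98 calls for brain and kidney. Contrasts with brain also carry its region markers: the striatal marker Adora2a was at −4.53 in brain and 0.26 in gastrocnemius, and Pax7, of midbrain development, at 4.05 and −0.10. Between brain and kidney Eva1a differed by 1.95 and Tfap2b by 4.44. Between brain and gastrocnemius the effect was higher in brain for the Myh14 model by 6.17, Irs2 by 2.72, Hoga1 by 2.67 (2.665), Pax7 by 4.08, Irx3 by 2.95, Sphk1 by 3.12, Il20rb by 5.26, Kdsr by 1.12, Natd1 by 1.11 (1.115), Wars by 1.17, Slc15a4 by 1.18 and Tprn by 2.75 (2.755). In the same comparison the difference was −6.18 (−6.185) for Sh3rf2, −2.71 for Map3k15, −1.50 for Arhgap18, −4.82 for Adora2a, −3.17 for Musk, −1.21 for C130074G19Rik and −1.64 for Trim68. Between kidney and gastrocnemius the Myh14 model differed by 6.40 and Irs2 by 2.85. Of the 19 genes of brain and gastrocnemius, the counts no longer past the threshold without control libraries 1, 2 and 3 and SeMSNs libraries 1 and 2 of every tissue in turn were 14 (adjusted p 0.106 to 0.187), 13 (0.0515 to 0.227), 1 (Tprn, 0.0505), 19 (0.0884 to 0.407) and 17 (0.151 to 0.286). Of the 2 of brain and kidney they were 1 (Tfap2b, 0.101), 2 (0.0848 and 0.15), 2 (0.186 and 0.261), 2 (0.33) and 2 (0.402). Of the 2 of kidney and gastrocnemius both were lost without control libraries 1 and 2 and SeMSNs library 1 (0.0755 to 0.378), Irs2 without SeMSNs library 2 (0.0644) and the Myh14 model without SeMSNs library 3 (0.0873). Of 30 relabellings of the 18 libraries, the real labels included, 7 gave at least the 2 genes of brain and kidney (highest other 6), 4 gave at least the 19 of brain and gastrocnemius (highest other 87) and 6 gave at least the 2 of kidney and gastrocnemius (highest other 11), so chance was not excluded for any of these counts. The 3 other relabellings with at least 19 genes, the one with 87 included, kept the real brain labels, and the highest count with other brain labels was 11.

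In brain, region markers differed between SeMSNs and control libraries. A piece with more cerebellum and hindbrain is a candidate explanation for SeMSNs libraries 1 and 2: 6 tested patterning genes of midbrain and hindbrain outside the fixed lists had medians of 3.18 and 3.05 log2 units above the control mean there, and 0.04 in SeMSNs library 3. Less striatum and hypothalamus in the SeMSNs pieces may account for the lower markers: 9 of 10 genes of these regions outside the marker lists were lower, with a median log2 fold change of −2.12 and library medians of −2.26, −1.82 and −1.44, against 0.10, −0.93 and 0.80 in controls. An effect of SeMSNs on regions or neurons was not tested and stays open. The 10 splits of the brain libraries are too few for a share under 0.05; the real split called 1 gene and 15 lists, 3 and 2 splits gave as many, and the highest other split gave 1 and 16.

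In gastrocnemius, Sik1, Irs2 and immediate early genes were lower with SeMSNs, though the immediate early list was not past the threshold by camera with an estimated correlation (adjusted p = 0.501). A different share of slow fibres was argued against for Sik1 and Irs2. With the slow fibre score as a covariate they were at −2.20 ± 0.234 (SE) and −2.81, with adjusted p values of 0.0216 and 0.0225 by edgeR. The median of the immediate early genes was then −1.21, with a bootstrap interval of −1.73 to −0.95. The bootstrap intervals here and below resampled the genes of a list, not the libraries, so they do not measure the spread between libraries. With the fast IIb fibre score instead that median was −1.61, and Sik1 and Irs2 were at −2.28 and −2.50, with adjusted p values of 0.326 and 0.412 by edgeR. A different feeding state at death cannot be told apart, since 9 fasting-induced genes outside the fixed lists had a median of −0.27 (−0.269), between the bounds of −0.3 and 0, with 6 lower and quartiles of −0.45 and 0.36, SeMSNs library 3 at 0.15 and the others at −0.45 and −0.49; with Irs1, which is in a fixed list, the median was −0.34 (−0.336). Handling or the time of day could also be involved and cannot be told apart from the treatment: the medians of the immediate early genes were −0.39 in brain and −0.59 in kidney, the first with SeMSNs library 3 at 0.12 and the second resting on control library 3, without which its direction reversed (adjusted p 0.827). Clock genes also bear on the time of day, and they differed between tissues. In kidney 0 of 20 tested members had an unadjusted p under 0.05 by edgeR. In gastrocnemius 1 of 19 was higher and 5 were lower by that measure. In brain 1 of 20 was higher and 2 were lower. These counts do not decide the question. The 10 splits are too few for a share under 0.05. The real split called 3 genes and 15 lists, 2 and 3 splits gave as many, and the highest other split gave 4 and 17.

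For the effect common to the tissues 165 genes passed, and the oxidative phosphorylation list was higher in each tissue, though not past the threshold in any with an estimated correlation (adjusted p = 0.727, 0.998 and 0.566 in brain, kidney and gastrocnemius) nor in brain without SeMSNs library 3 (0.101) or in kidney without control library 2 or 3 (0.265, 0.365), and reversed in kidney without SeMSNs library 2 (0.745); of 30 relabellings drawn in each tissue on its own only the real one (1 of 30) gave as many and the highest other gave 4, which excludes chance labels only if libraries of different tissues are independent, and with equal numbers kept together the 10 splits are too few for a share under 0.05 (real 165, highest other 5). Gene length bias as the whole cause was argued against in gastrocnemius and brain, where the list's medians of 0.47 and 0.29 became 0.34 (0.345; interval 0.30 to 0.41) and 0.24 (0.239; 0.17 to 0.26) after subtraction of the length trend, and for the common effect, where 125 genes passed with each library's trend removed, 114 of them shared with the 165, although the list's common median went from 0.27 to 0.18 (0.185) and the median length was 3415 bases for genes that rose and 7152 for genes that fell. In kidney length bias stays open as a candidate explanation: the list's median of 0.11 (interval 0.07 to 0.15) went to 0.05 (0.00 to 0.11), and the list was no longer past the threshold with the trend removed (adjusted p 0.323). A different share of fast fibres cannot be told apart from the treatment in gastrocnemius. Fast IIb fibre genes rose and slow fibre genes fell there (medians 0.57 and −0.96). Whether such a shift would raise or lower the oxidative phosphorylation list was not tested. With the fast fibre score as a covariate the list's median was 0.38 with an interval of 0.31 to 0.48, which includes values under the bound set for excluding it. In that fit Sik1 was at −2.28 with its SE up from 0.218 to 0.399 (adjusted p 0.326 by edgeR). The score itself separated the groups, at −0.246, −0.622 and −0.0295 in controls and 0.319, 0.197 and 0.381 with SeMSNs. The covariate thus moved with the treatment, and the lost call of Sik1 says nothing for or against a share of fibres. An effect of SeMSNs in all 3 tissues stays open, and so does any difference in housing, handling or collection between the groups, which was not tested. Brain region markers also enter the mean over the tissues, and their part in it was not tested.

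In kidney the 10 splits are too few for a share under 0.05. The real split called 1 gene and 10 lists, 6 and 10 splits gave as many, and the highest other split gave 2 and 22. Every other kidney split called more lists than the real one, at least 12. Other splits called 9 to 16 lists in brain and 8 to 17 in gastrocnemius, where the real ones called 15. The counts of lists passed by camera with the preset correlation therefore do not set the real groups apart.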

How the results depend on the processing

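The robust fit, removal of the length trend, and leaving out both SeMSNs libraries 1 and 2 were alternatives chosen after seeing the data; limma on log2(FPKM + 1) was the test written beforehand. Unless a value shows it, the cause of a change was not tested. Fewer libraries lower the power of each fit that leaves 1 out, and simulated 2-fold changes were called for 13%, 41% and 12% of genes in brain, kidney and gastrocnemius.

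The 1 gene called in brain became 216 with all 18 libraries in one fit, 3383 with library weights, 2 with the replicate block (a block for libraries that share only a number), 668 by DESeq2, 0 without both SeMSNs libraries 1 and 2 (a fit with 1 SeMSNs library, assumed to vary like the controls; 0 already without either), and 899 by an unadjusted p with a 2-fold change. The 1 gene in kidney became 0 by limma on log2(FPKM + 0.1), + 0.01 and + 1, on TPM and with no trend or robust step, 0 with the block and 0 with the length trend removed; it became 5 with no filter, 3 with a mean FPKM of at least 5, 3 by the robust fit, 26 by DESeq2 and 160 by an unadjusted p with a 2-fold change. The 3 genes in gastrocnemius became 5 by limma on log2(FPKM + 0.1), + 0.01 and + 1, 31 with no filter, 18 on TPM (2 higher, 16 lower), 197 with all 18 libraries, 108 with library weights, 162 by DESeq2 and 445 by an unadjusted p with a 2-fold change. No list passed with an estimated correlation in any tissue (0 in each), and by fry 1 passed in brain (adipocytes, not among the 15 that passed by camera), 0 in kidney and 0 in gastrocnemius; the kidney count of 10 became 5 after quantile normalisation and 6 with the length trend removed.

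The common effect went from 165 genes to 87 with a mean FPKM of at least 5, 297 after quantile normalisation and 8 with the block. Differences between brain and kidney went from 2 to 0 with log2(FPKM + 0.1) and with a mean FPKM of at least 5. Those between brain and gastrocnemius went from 19 to 2 with each of these, 6 after quantile normalisation, 1 with the replicate number within each treatment as a random effect, 3 with the block and 1 by limma on log2(FPKM + 1). Those between kidney and gastrocnemius went from 2 to 4 with log2(FPKM + 0.1) and 0 with the block. The median over all genes moved by 0.113 on TPM in brain and by 0.121 with log2(FPKM + 0.1) for brain against gastrocnemius.

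With 1 library left out, counts of genes ranged from 0 to 2852 in brain, 0 to 4 in kidney, 0 to 335 in gastrocnemius and 1 to 640 for the common effect; differences ranged from 0 to 340 for brain and kidney, 1 to 575 for brain and gastrocnemius and 0 to 123 for kidney and gastrocnemius. Counts of lists ranged from 10 to 15 in brain, 10 to 16 in kidney and 15 to 19 in gastrocnemius. Correlations of effects ranged from 0.0728 to 0.0994, 0.0749 to 0.15 and 0.0789 to 0.365. In that fit with 1 SeMSNs library, without both SeMSNs libraries 1 and 2, Calb1, Stat2 and Ifit3b were near 0 with the other sign, at −0.08 (−0.079), −0.04 (−0.0356) and −0.02 (−0.022), which says nothing of a reversal between groups. Lists that reversed, with that adjusted p and the range over the 6 fits with 1 library left out, were in brain ribosomal proteins without SeMSNs library 3 (0.761; 8.94e-08 to 0.761). In kidney they were immediate early genes (0.827; 3.61e-08 to 0.827) and glucocorticoid genes (0.411; 0.00129 to 0.688) without control library 3, adipocytes without SeMSNs library 1 (0.000436; to 0.692 without control library 1), and oxidative phosphorylation (0.745; 0.000436 to 0.745) and ribosomal proteins (0.468; 4.71e-05 to 0.922) without SeMSNs library 2. In gastrocnemius they were red blood cells without control library 2 (0.00993; 0.00427 to 0.857) and fibroblasts without control library 3 (0.271; 4.54e-05 to 0.389). Of the values of named genes under alternatives, 2130 of 2357 in brain, 1584 of 1633 in kidney and 1827 of 1926 in gastrocnemius kept their direction and their side of the threshold. A further 10, 18 and 4 changed sign without a call, from an unadjusted p of 0.05 or more. Few of these genes were called, so the kept share says little of calls. The call was lost in 7 of 24 alternatives for Ctdsp2 and 12 of 23 for Eva1a. In gastrocnemius it was lost in 5 of 23 for Sik1, 4 of 23 for Irs2 and 1 of 22 for the Myh14 model. Of values of genes named over the tissues, 328 of 515 kept both and 163 lost the call. Of values of lists, 513 of 638 in brain, 445 of 608 in kidney and 410 of 544 in gastrocnemius kept both. With the block the red blood cell and precursor lists of brain had adjusted p values of 0.116 and 0.0505 and the endoplasmic reticulum list of gastrocnemius 0.0628, and for the common effect F2r, Ppox, Clybl, Kdsr and Irs2 had 0.0642 to 0.0878.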

Other observations

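Some clock genes, named here after their values were seen, were lower in gastrocnemius although their list was not past the threshold. Arntl, Cry2 and Per1 had log2 fold changes of −1.14, −1.03 and −0.69 with SeMSNs and passed adjusted over the list alone, and 0 of the 19 tested members passed over all genes tested by edgeR. Dbp, an output gene of the clock, was at 1.04 and did not pass.

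Ctdsp2 was between 22.3 and 24.2 CPM in brain controls and between 106 and 127 CPM in SeMSNs brain libraries. In gastrocnemius it was at 34.9, 162 and 94.7 CPM in controls and at 112, 120 and 126 CPM with SeMSNs, so a low and a high level occurred in libraries of both groups in kidney and within controls in gastrocnemius. Gpx1 was at 2470 CPM in kidney SeMSNs library 2, against 373 CPM in SeMSNs library 3.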
